A study of Mus musculus with 5 samples.

How the data were processed

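Total RNA of mouse iPS cells was amplified, labelled with biotin with the Illumina TotalPrep-96 kit and hybridized to Illumina mouse bead arrays, per the labels. There were 5 arrays, 1 for each condition. The deposited intensity of a probe is the mean signal of its beads, per the file headers, with no background subtraction and no normalization between arrays, and its bead standard error is in the same intensity unit. The deposited detection p-value of each probe compares it with the negative control probes of the same array, per the file headers, and the deposited bead numbers give the beads behind each probe. The authors also deposited a matrix of log2 values for 19665 probes, which were quantile-normalized between the arrays and not centred per gene, as read from the values themselves: each array had the quantiles of the others and a rank correlation of 1 with its own signal. The lumi package is named in the submitters' notes, with no version or settings. Those values differed by 0.148 log2 units at most from a plain quantile normalization of the same probes, and 415 of the probes were detected on no array. Probes had a median of 43 to 44 beads, and the bead standard error of detected probes had a median of 4.76% to 4.90% of the signal.

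The probe signals were background-corrected and normalized with neqc of limma 3.58.1 in R 4.3.3, which fits the background from the detection p-values, adds an offset of 16 and applies quantile normalization. Probes with a detection p under 0.01 on at least 1 array were kept, and each gene was represented by the brightest of its kept probes. Probe names were brought up to date through the Entrez identifier for 29586 probes and through the transcript accession for 2759, and 12936 kept the name in the file. The reference held gene names and positions without a genome sequence, so the probes were not aligned and no positions are given for them. A gene was counted in a comparison if the array with the higher value detected it. Differences of log2 values were called at 1.4-fold, from the study's design. Standard errors were computed from the bead standard errors of the 2 arrays. A gene's fold is given as a lower bound where the other array did not detect its probe.

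The comparisons were each withdrawal against the maintained array, each re-addition against the withdrawn array of the same duration, the withdrawn arrays against each other, and each re-added array against the maintained array. Genes at least 1.4-fold lower in both withdrawals and higher in both re-additions, and the converse, were collected as GCSF-dependent. The count was set beside all 60 distinct assignments of the arrays and 100 simulations of unchanged arrays, whose noise was drawn by signal level from the difference between the re-additions. The maintained array gave none of that noise. Re-addition over both durations was tested with limma on 4 arrays with duration as a block and Benjamini-Hochberg adjustment. The medians of 23 gene lists were placed among 10000 random lists of the same size and mean signal. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the remaining steps.

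The comparisons, thresholds, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named the 5 largest rises and falls of each main comparison, the GCSF-dependent genes (all where a direction had 30 or fewer, otherwise the 15 with the largest smallest change), up to 4 members of each gene list with the largest mean change, and 16 genes chosen beforehand: Socs3, Stat3, Klf4, Klf5, Tfcp2l1, Gbx2, Pim1, Pim3, Junb, Myc, Nanog, Esrrb, Pou5f1, Sox2, Csf3r and Il6st. The steps were tested on simulated data of 5 arrays with 200 of 13618 genes changed. The 4-comparison rule, run here with every gene taken as detected, found 37.1% of genes changed 1.5-fold, 92.3% of those changed 2-fold and 100% of those changed 3-fold, with 10 false calls. These shares and false calls therefore do not describe the rule with the detection requirement used on the data. The limma test with a block found 0.0%, 33.8% and 89.2% with 0 false calls, and with an intensity trend 50.0%, 81.5% and 96.9% with 6 false calls among 157. On unchanged simulated arrays 6.3% of 460 list medians lay outside the central 95% of random lists.

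The alternatives were the authors' normalized values, no background correction, a common median or cyclic loess in place of quantile normalization, no detection filter, probes detected on all 5 arrays, the mean of a gene's detected probes, thresholds of 1.2-fold and 2-fold, a requirement of 2 bead standard errors, list means, pairs of comparisons without a shared array, each duration alone, and limma without a block, with 3 states, with an intensity trend or at an adjusted p of 0.1. Probes detected on no array were left out of the main values, because their signal could not be told from background.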

Results

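Mouse induced pluripotent stem (iPS) cells carrying the GY118F transgene were profiled on Illumina bead arrays before, during and after withdrawal of granulocyte colony-stimulating factor (GCSF). Per the labels, the cells were female, of mixed 129 and MF1 background, and had been reprogrammed from adult neural stem cells. GY118F is known as a chimeric receptor that couples GCSF to the signalling part of gp130, the receptor subunit used by leukaemia inhibitory factor, which activates the kinase JAK and the transcription factor STAT3. The cells had been derived and were kept in N2B27, a serum-free medium, with GCSF. The 5 conditions were GCSF maintained, GCSF withdrawn for 12 h, GCSF withdrawn for 24 h, and GCSF given back for 2 h and 40 min after each of the withdrawals, as the sample labels give it; the column names of the signal file carry another number of hours. Each condition was measured on 1 array, so no difference below has a replicate check, and the number of arrays limits the precision. The labels do not say whether the maintained culture was sampled alongside the withdrawn ones, and no array had a mock re-addition. Effects of time in culture or of handling can thus not be told apart from those of GCSF, also for the genes called GCSF-dependent. The errors given are standard errors over the beads of a probe, which cover the measurement on the array only; their median was 0.13 log2 units for a difference between 2 arrays. Each array gave a signal for 45281 probes, with a total signal of 20442614 with GCSF maintained, 20962682 after 12 h and 18135344 after 24 h of withdrawal, and 20727959 and 18526154 after the respective re-additions. Between 16677 and 17452 probes per array were detected, and the 19250 probes detected on at least 1 array stood for 13618 genes. A gene is said below to have risen or fallen where its normalized signal differed by at least 1.4-fold, the threshold of the study's own design. That is 0.49 log2 units, so a rise or fall with a bead standard error near the median exceeds 2 such errors by the threshold alone. The shares and numbers of changes past 2 bead standard errors given below are thus no separate check on the changes. Where the dimmer of the arrays did not detect the probe, the change is given as at least the fold over the lowest detected level of that array, a bound that can lie below the threshold, and no p-value is given across genes for single arrays. Values are those of a gene's brightest probe, and for Car14, Dusp4, Irf1, Irf9, Klf4, Muc1, Nkx1-2, Nodal, Pim1, Rasgrp2, Sbno2 and Wnt8a at least 1 other detected probe fell short of 1.4-fold in a withdrawal or re-addition where the brightest passed. Some of these dimmer probes changed with the opposite sign. Among them, that of Pim1 had log2 changes of 0.46 after 12 h of withdrawal and -0.28 in the re-addition after it. That of Car14 had -0.28 after 12 h and that of Irf9 0.28 after 24 h of withdrawal. Csf3r, the endogenous GCSF receptor gene, had 5 probes, and none was detected on any array; whether these probes match the transgene is not known.

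The first comparison asked which transcripts changed when the cells lost GCSF for 12 h. Genes that answer to STAT3 and gp130 signalling fell. Of the 26 detected genes of this list, 15 fell and 0 rose, with a median log2 change of -0.56, at percentile 0.0 of 10000 random lists. Socs3, the feedback inhibitor of JAK signalling, fell 3.62-fold (log2 change -1.85 ± 0.10), and Junb, a subunit of the AP-1 transcription factor, had a log2 change of -1.58 ± 0.12. Zfp36, which directs the decay of mRNAs, fell 2.68-fold (-1.42 ± 0.09), and Bcl3, a nuclear IκB family member, fell 3.37-fold (-1.75 ± 0.11). Stat3 itself fell 1.89-fold, Icam1, a cell adhesion molecule, fell 2.25-fold, and the kinase genes Pim1 and Pim3 fell 1.74-fold and 1.60-fold. The steepest falls by normalized value were those of Serpina3h (5.19-fold), Muc1 (at least 3.93-fold), Chil1 (3.92-fold), Gsc (3.85-fold) and Socs3. Serpina3h belongs to a family of near-identical serine protease inhibitor genes, and which of them its probe reads was not checked.

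Among pluripotency factors after 12 h, Tfcp2l1, a transcription factor of the naive state, fell 1.46-fold (log2 change -0.55 ± 0.11). Klf4 and Klf5 had log2 changes of -0.24 ± 0.10 and -0.42 ± 0.10, and Gbx2 one of -0.17 ± 0.10, all short of 1.4-fold. Of the 19 detected genes of the naive pluripotency list, 1 fell and 2 rose, and their median of -0.12 lay at percentile 0.635 of random lists. Nanog (-0.12), Esrrb (-0.43), Pou5f1 (0.04) and Sox2 (0.13) stayed under the threshold, and the core pluripotency list had a median of 0.10, at percentile 93.5; 2 of its 14 genes fell, Tdgf1 (2.17-fold) and Fgf4 (1.47-fold), and 0 rose. Genes of the post-implantation epiblast were higher. Of 14 detected, 6 rose and 0 fell, with a median of 0.45 at percentile 100 of random lists. Wnt8a rose by 1.58 log2 units, Fgf5 2.03-fold, Fgf15 2.03-fold and Car14 1.80-fold. Fst, which encodes follistatin, rose at least 3.23-fold, Vrtn 3.09-fold and Tal2 2.93-fold. Nkx1-2 (at least 2.16-fold) and T, the mesoderm gene brachyury (at least 2.21-fold), rose from below background, which leaves their rank open.

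Over all genes, 549 rose and 733 fell after 12 h, of 12653 measured, and 86.0% of these changes exceeded 2 bead standard errors. At 2-fold, 44 rose and 76 fell. Without background correction 112 genes were higher and 186 lower by 1.4-fold. On the authors' deposited normalized values 100 genes were higher and 164 lower by 1.4-fold, and Pim1, Fgf5, Fos and Irf9 fell short of it.

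After 24 h of withdrawal, the question of the 12 h comparison was asked again at the longer duration. Of the 26 detected STAT3 and gp130 response genes, 16 fell and 0 rose, and the median log2 change was -0.75, at percentile 0.0 of random lists. Socs3 fell 4.39-fold (-2.13 ± 0.10) and Bcl3 4.54-fold (-2.18 ± 0.14). Junb fell 2.73-fold, Zfp36 2.93-fold and Stat3 2.02-fold. Of the naive pluripotency genes 7 of 19 fell and 0 rose, with a median of -0.37 at percentile 0.0. Among them, Klf4 fell 1.43-fold (-0.52 ± 0.09), Klf5 fell 1.78-fold (-0.83 ± 0.11) and Tfcp2l1 fell 1.85-fold (-0.89 ± 0.10). Gbx2 (-0.42), Esrrb (-0.46), Nanog (-0.07), Pou5f1 (-0.39) and Sox2 (-0.38) did not pass 1.4-fold, and the core pluripotency list had a median of -0.10 at percentile 3.27; 1 of its 14 genes fell, Tdgf1 (2.57-fold), and 0 rose. Of the 14 post-implantation epiblast genes, 11 rose and 0 fell, and the median was 0.81, at percentile 100. Fgf5 rose 2.51-fold, Fgf15 2.39-fold, Wnt8a 2.13-fold and Nodal, a TGF-beta family ligand, 1.74-fold, and Car14 rose by 0.97 log2 units.

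The steepest falls at 24 h among genes detected on both arrays were those of Chil1 (6.49-fold), Bcl3, Socs3, Fgg, which encodes a fibrinogen chain (4.22-fold), and Sp5, a zinc finger factor of the WNT target list (4.18-fold). Fst rose at least 3.10-fold, Slc46a3 2.80-fold, the actin genes Actc1 and Acta2 2.70-fold and 2.63-fold, and Idb2 at least 2.52-fold; Idb2 is the file's name for this probe and an older symbol of Id2, so that it and Id2 may be 1 gene read by 2 probes. Of the fibroblast and feeder cell markers, 3 of 8 detected genes rose, Thy1 (1.61-fold), Dcn (at least 1.39-fold) and Acta2, with a median of 0.32 at percentile 99.6; after 12 h Dcn (at least 1.78-fold) and Col6a1 (at least 1.22-fold) had risen and Acta2 had fallen 1.73-fold, with a median of 0.09. Over all genes 741 rose and 788 fell, of 12846 measured, and 85.7% of the changes exceeded 2 bead standard errors. Scaling of the arrays to a common median in place of quantile normalization gave 994 higher and 596 lower. The authors' deposited normalized values gave 133 and 199, with Klf4, Pim1, Lef1 and Fos short of 1.4-fold.

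GCSF was then given back for 2 h and 40 min, to ask which transcripts answer to it within that time. After 12 h without GCSF, 20 of the 26 detected STAT3 and gp130 response genes rose and 1 fell, with a median of 0.78 at percentile 100. Socs3 rose 3.65-fold (1.87 ± 0.11), Junb 3.53-fold (1.82 ± 0.12), Zfp36 3.38-fold (1.76 ± 0.09) and Stat3 2.81-fold (1.49 ± 0.13). Pim1 rose 1.67-fold, Pim3 2.02-fold and Il6st, which encodes gp130, 1.57-fold. The gene that fell was Myc, whose signal with GCSF back was no longer above background (at least 1.45-fold). Serpina3h rose 3.52-fold. Sbno2, a transcriptional corepressor, rose 3.75-fold by its brightest probe, while its other detected probe had a log2 change of 0.24.

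Of the naive pluripotency genes 3 of 19 rose in the re-addition after 12 h, and 0 fell. These were Klf4 (1.55-fold), Klf5 (1.49-fold) and Gbx2 (1.82-fold), all of which are also in the STAT3 and gp130 list. Tfcp2l1 had a log2 change of -0.19 ± 0.11, Nanog 0.18, Esrrb 0.05, Pou5f1 -0.22 and Sox2 -0.08, and the median of the list, -0.02, lay at percentile 42.4. Of the post-implantation epiblast genes 3 of 14 fell, namely Fgf5 (1.46-fold), Wnt8a (1.44-fold) and Nodal (1.54-fold), with a median of -0.15 at percentile 1.25. Epha2, a receptor tyrosine kinase, fell 2.11-fold. Rasgrp2 fell 2.10-fold by its brightest probe, while its other detected probes had log2 changes of -0.28 and -0.33. F730031O20Rik (at least 1.64-fold), Atp4a (at least 1.65-fold) and Dsg4 (at least 1.31-fold) ended below background. In all, 539 genes rose and 423 fell, of 12730 measured, and 78.1% of these changes exceeded 2 bead standard errors. At 2-fold, 40 rose and 8 fell. The authors' deposited normalized values gave 76 higher and 34 lower at 1.4-fold, without Myc, Pim1, Il6st, Fgf5, Wnt8a, F730031O20Rik, Atp4a and Dsg4, and quantile normalization without background correction gave 89 and 41.

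In the re-addition after 24 h without GCSF, 15 of the 26 STAT3 and gp130 response genes rose and 1 fell, with a median of 0.62 at percentile 100. Socs3 rose 4.35-fold (2.12 ± 0.09), Rgs16, a regulator of G protein signalling, 3.18-fold (1.67 ± 0.11), Zfp36 3.14-fold (1.65 ± 0.09), Tfap2c, an AP-2 transcription factor, 3.10-fold (1.63 ± 0.14) and Junb 2.97-fold (1.57 ± 0.15). These were the 5 largest rises among genes detected on both arrays. Stat3 rose 2.53-fold and Pim3 1.81-fold, whereas Pim1 and Il6st had log2 changes of 0.08 and 0.09. Myc was again the member that fell (at least 1.18-fold). Klf4 rose 1.58-fold, Klf5 1.79-fold and Gbx2 1.51-fold, the 3 risers among the 19 naive pluripotency genes. Tfcp2l1 had a log2 change of 0.00 ± 0.09, Esrrb -0.03, Nanog -0.08, Pou5f1 -0.09 and Sox2 0.22. Of the post-implantation epiblast genes 3 of 14 fell, among them Nodal (1.93-fold) and Wnt8a (1.56-fold), and the median was -0.14 at percentile 0.78. Ube2r2 (at least 1.40-fold), Sgsh (at least 1.46-fold), Sybu (at least 1.30-fold), Spata3 (at least 1.18-fold) and Fgf21 (at least 1.66-fold) also fell, and as all of them ended below background their rank is not established; Msc, detected on both arrays, had a log2 change of -0.97. In all, 471 genes rose and 389 fell, of 12817 measured, 26 and 5 of them by 2-fold, and 78.0% of the 1.4-fold changes exceeded 2 bead standard errors. Falls were scarcer on the authors' deposited normalized values, with 60 genes higher and 9 lower, and without background correction, with 62 and 15. Myc and the 5 genes that ended below background did not pass 1.4-fold on the authors' values.

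The study's own rule for potential targets asked for 1.4-fold in all 4 of these comparisons. By it, 55 genes fell in both withdrawals and rose in both re-additions, and 51 of them did so by more than 2 bead standard errors each time. Socs3 led this group, with a smallest change of 1.85 log2 units. Next came Junb, Zfp36, Serpina3h, Tfap2c, Bcl3, LOC100047268, Rgs16, Icam1, Sbno2, Sp5, the haematopoietic factor Gata2, Stat3 and Ier5l. Gpr146, an orphan receptor gene, was below background on both withdrawn arrays, which leaves its rank open (at least 1.82-fold, 1.93-fold, 2.04-fold and 1.70-fold in the 4 comparisons). Tfap2c had log2 changes of -1.33, -1.75, 1.35 and 1.63 in the order withdrawal 12 h, withdrawal 24 h and the respective re-additions, Rgs16 had -1.29, -1.19, 1.56 and 1.67, and Gata2 had -1.52, -1.89, 1.27 and 0.93. Pim3, Fos, Tdgf1, Gsc, Irf9, Muc1 and Fgg, named here from gene lists or as extremes, also met the rule. Klf4 and Klf5 did not, because their changes after 12 h of withdrawal were under 1.4-fold. Only 10 genes had the converse pattern: Epha2, Tal2, Rad54l2, Prickle1, Cabs1, Timp4, Rassf6, Wnt8a, Hoxa5 and Msc. Epha2 had log2 changes of 1.26, 0.95, -1.08 and -0.74, and Tal2 of 1.55, 1.14, -0.81 and -0.73. Rad54l2 and Cabs1 were detected on the withdrawn arrays alone, with bounds of at least 1.13-fold and 1.11-fold for the 12 h withdrawal.

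**Figure D1:**
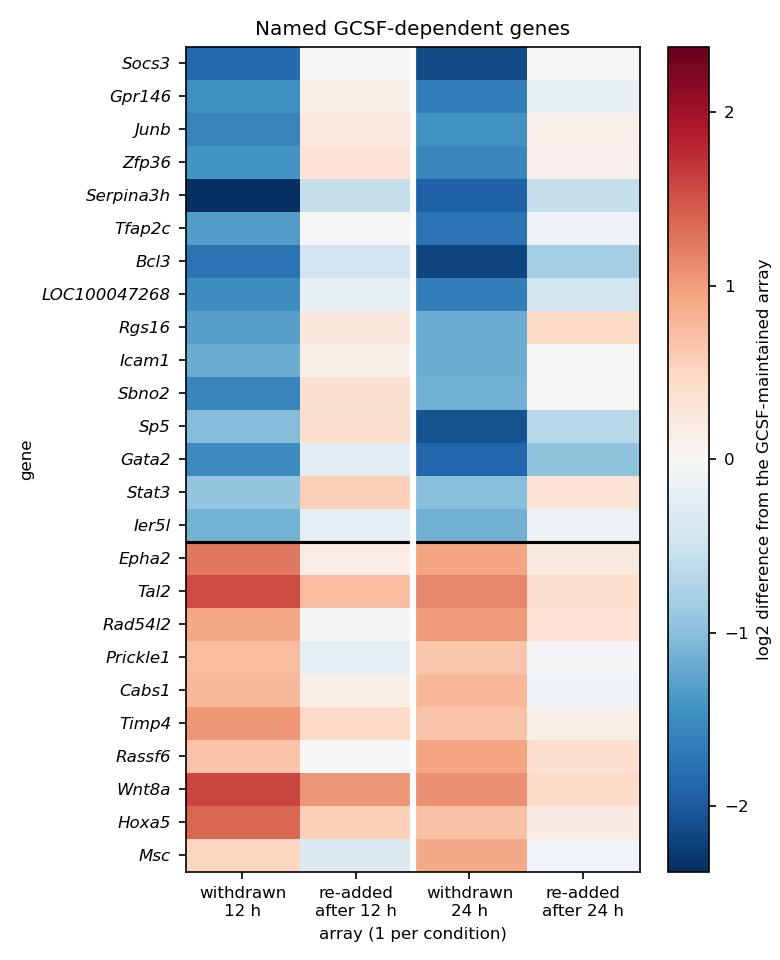
Log2 difference from the GCSF-maintained array (colour) for 15 genes that fell and then rose, taken by their smallest normalized change (above the line), and all 10 genes that rose and then fell (below it), on the 2 withdrawn and the 2 re-added arrays, 1 array per condition. Socs3 went from -1.85 to 0.01 with re-addition after 12 h and from -2.13 to -0.01 with re-addition after 24 h.

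A withdrawal and the re-addition of the same duration share the withdrawn array, whose noise enters them with opposite signs. In 100 simulations of 5 unchanged arrays the rule picked 1 gene on average in the first direction (at most 5) and 1.01 in the converse one (at most 4). Their noise was drawn anew for each gene and array among genes of like signal. A gene that is noisy on every array is thus not reproduced, and the simulated numbers can be too low. The noise came from the withdrawn and re-added arrays alone, so a noisier maintained array is not reproduced either. Of the 60 distinct assignments of the 5 arrays to the 5 conditions, the actual one gave the highest count of genes that fell and then rose; the next gave 53. The 6 assignments with the withdrawn arrays in the withdrawn places gave 45 to 55, and the other 54 gave at most 29. For the converse pattern 26 of the 60 assignments gave 10 or more genes, up to 33, so passing the simulated maximum of 4 does not set that pattern apart. With the authors' deposited normalized values, 26 genes fell and then rose, all of them among the 55, and 2 had the converse pattern, both among the 10.

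Comparisons that share no array were set against each other to see how far the responses recurred. Of 409 genes that rose in the re-addition after 12 h and 333 that rose in the re-addition after 24 h, among 12162 genes measured in both, 94 were shared, where independent lists would share 11.2. Of the genes that fell, 26 were shared, against 7.36. Genes that fell after 12 h of withdrawal and rose in the re-addition after 24 h numbered 99, against 16.2 for independent lists, and those that fell after 24 h and rose in the re-addition after 12 h numbered 114, against 21.2. The converse overlaps were 35 against 9.99, and 48 against 16.4. Overlaps in the wrong direction exceeded independent lists too, with 22 against 12.8 and 29 against 17.6 for genes that fell in the withdrawal and 19 against 9.01 for genes that rose in the re-addition after 12 h and fell in the other. Across all genes, which are not independent replicates, the correlation was weak: r was 0.17 between the re-additions, -0.14 between withdrawal for 12 h and re-addition after 24 h, and -0.09 for the other pair. The 2 withdrawals had r = 0.61, but they share the maintained array, and unchanged arrays simulated with that array shared gave r = 0.50; the covariance was 0.059 beside a simulated 0.029. They shared 372 genes that fell and 196 that rose, where independent lists would share 46.4 and 19.5 and simulated unchanged arrays, with the maintained array shared, had 60.6 and 37.8. Genes noisy on every array are not reproduced in these simulated numbers either, so they can be too low. Nor does the simulated noise hold any from the maintained array, which the withdrawals share. On that array 154 genes were at least 1.4-fold higher than on every other array, against at most 63 for another. The excess of shared genes and of r over the simulated values can thus be noise of the maintained array.

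**Figure D2:**
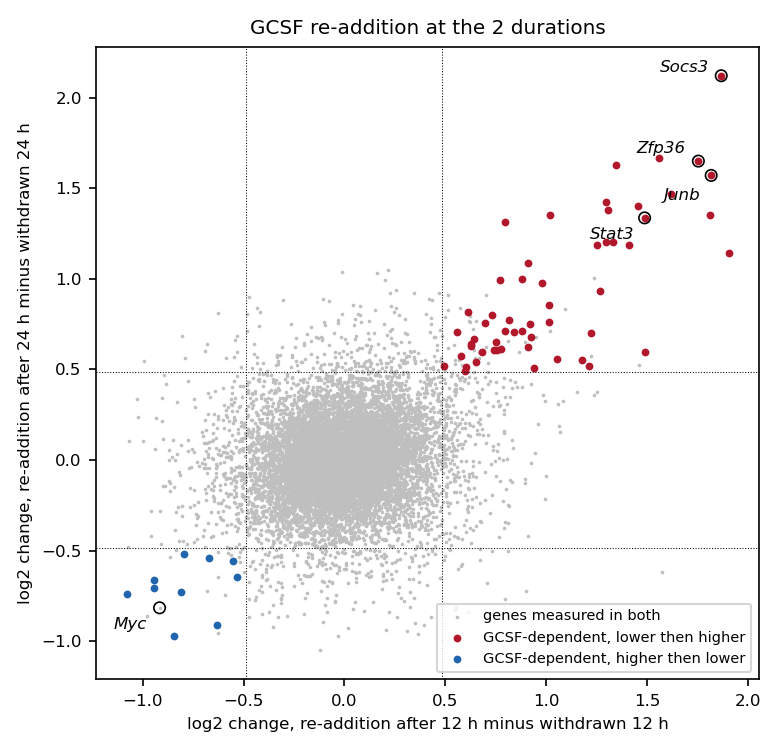
Log2 change on re-addition of GCSF after 12 h (horizontal axis) and after 24 h (vertical axis) of withdrawal, 1 point per gene measured in both, with dotted lines at 1.4-fold. The 55 genes that fell and then rose are in red, the 10 with the converse pattern in blue, and circled genes are named; Myc ended below background in both re-additions (at least 1.45-fold and 1.18-fold lower).

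Some genes passed 1.4-fold in both re-additions without having passed it in either withdrawal. There were 25 that rose, among them Gbx2 (log2 changes 0.86 and 0.60) and the interferon regulatory factor gene Irf1 (0.70 and 0.91), where simulated unchanged arrays gave 6.19 on average and at most 16. There were 12 that fell, among them Myc, where simulated unchanged arrays gave 4.63 on average and as many as 12. The simulated numbers can be too low for both groups, since genes noisy on every array are not reproduced. Only 9 of the 25 and 6 of the 12, which do not include Myc, were detected on both arrays in both re-additions. In the withdrawals Gbx2 had log2 changes of -0.17 and -0.42, Irf1 of -0.31 and -0.43, and Myc of 0.27 and 0.01. For genes such as Irf1 the threshold alone can make a fall and return look like a response to re-addition only.

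The effect of re-addition over both durations was tested with limma, with duration as a block and 1 residual degree of freedom per gene, so that the spread is that between durations and not between replicates. By that test 0 of 13618 genes passed an adjusted p of 0.05; the smallest adjusted p from limma was 0.11, and 1065 genes had an unadjusted p under 0.05. With limma's intensity trend for the prior variance, 106 genes rose and 30 fell. Socs3 led them (log2 change 1.99 ± 0.09, limma adjusted p = 1.13e-21), followed by Zfp36 (1.70 ± 0.11) and Junb (1.69 ± 0.11), and Prickle1 (-0.82 ± 0.11) led the genes that fell. The errors here are those of the limma fit, not bead errors. That fit had 44.8 prior degrees of freedom beside the 1 residual one, against 4.11 without the trend. Its errors and p-values therefore rest mainly on the spread of other genes of like signal, not on a gene's own spread.

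The 24 h and 12 h withdrawn arrays were compared directly to see how the levels moved on between these times. T and Nkx1-2, detected at 12 h and not at 24 h, were lower at 24 h by at least 2.19-fold and 2.13-fold, and Sp5 was lower by 2.04-fold. Socs3 (-0.28), Stat3 (-0.09), Junb (0.14) and Zfp36 (-0.13) differed by less than 1.4-fold, and so did Klf4 (-0.28), Klf5 (-0.42) and Tfcp2l1 (-0.34). Sox2 had a log2 difference of -0.50 by its brightest probe and of -0.09 by another probe of similar signal, and Pou5f1 had -0.43. Acta2 was higher by 2.19 log2 units and Actc1 by 1.86. In all, 619 genes were higher and 492 lower at 24 h, of 12613 measured, and scaling to a common median gave 846 and 360. On the authors' deposited normalized values 114 genes passed 1.4-fold.

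Each re-added array was also compared with the maintained array, to see how far levels returned. Socs3 had log2 differences of 0.01 and -0.01 from the maintained level, Icam1 of 0.16 and 0.02, and Tfap2c of 0.02 and -0.12. Stat3 exceeded the maintained level after 12 h (0.57), and was at 0.32 after 24 h. Bcl3 remained lower after 24 h (-0.80) and Gata2 likewise (-0.96). Chil1 stayed lower after both (3.90-fold and 8.21-fold), and so did Tfcp2l1 (-0.74 and -0.89). Fgf5 (0.48 and 1.09), Fgf15 (0.62 and 1.16) and Car14 (0.68 and 1.13) were above the maintained level. Of the 372 genes that fell in both withdrawals, 55 rose in both re-additions, 77 in 1 of them and 240 in neither, and 154 were still lower on both re-added arrays than on the maintained one. Of the 196 that rose in both, 10 fell in both re-additions, 50 in 1 and 136 in neither, and 74 were still higher on both. After re-addition at 12 h 607 genes were higher and 682 lower than with GCSF maintained, and after re-addition at 24 h 836 and 786, which became 1099 and 572 with scaling to a common median. The 500 genes that differed the same way on both re-added arrays were 86 on the authors' deposited normalized values.

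Of 23 gene lists fixed before the data were examined, several others stood apart from random lists of the same size and mean signal, which is a description of these libraries. Of the 92 medians, 33 lay outside the central 95% of random lists, where 4.6 would if the medians were independent and the genes of a list unrelated. The comparisons share arrays and some lists share genes, so 33 is not a count of separate responses. Cholesterol synthesis genes had a median of 0.33 after 12 h (2 of 13 rose, percentile 100) and 0.18 after 24 h (0 rose, percentile 99.7), and Idi1 had a log2 change of 0.48 at 12 h. The ERK immediate-early and feedback list had a median of 0.30 after 12 h, at percentile 100, and of 0.02 after 24 h, at percentile 55.4. Within it, Dusp4 rose in both withdrawals (1.42-fold and 1.76-fold) by its brightest probe, though not by 2 of its 3 other detected probes, and Egr2 rose at least 1.60-fold and 1.93-fold, whereas Fos fell 1.52-fold and 1.85-fold and rose 1.74-fold and 2.48-fold in the re-additions. The 6 detected BMP and SMAD1/5 targets had a median of 0.66 after 12 h at percentile 100; Id2 rose in both withdrawals (1.65-fold and 1.46-fold) and Id1 fell in both (1.68-fold and 2.51-fold). WNT pathway targets had medians of 0.30 and 0.29 in the withdrawals, at percentiles 99.7 and 99.1, with Lef1 rising 1.88-fold and 1.43-fold and Sp5 falling in both. For NODAL and SMAD2 targets the median was 0.27 after 12 h (percentile 99.7) and -0.20 in the re-addition after 24 h (percentile 0.45).

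Interferon targets had medians of 0.20 and 0.19 in the re-additions, at percentiles 98.8 and 99.3, with 3 of 10 genes rising each time and 1 falling after 24 h. Irf9 fell 1.64-fold and 1.59-fold and rose 1.52-fold and 1.43-fold. Unfolded protein and amino acid stress genes had a median of 0.15 after 24 h (percentile 99.5) and -0.17 in the re-addition after 24 h (percentile 0.0), where 1 of 14, Chac1, fell 1.62-fold. The MYC and ribosome biogenesis list had a median of 0.13 after 12 h (percentile 99.4) and -0.11 in the re-addition after 24 h (percentile 0.81). Cell cycle genes had a median of 0.15 after 24 h (percentile 99.5), with 0 of 18 past 1.4-fold. Mesoderm genes had a median of -0.44 after 24 h (percentile 0.81), with Gsc as the 1 of 6 that fell. Endoderm genes had medians of 0.21 and 0.21 in the re-additions (percentiles 98.8 and 98.5), with 0 of 8 past 1.4-fold, and trophectoderm genes had 0.19 in the re-addition after 12 h (percentile 97.6). The DNA demethylation and germ line list had a median of -0.23 after 24 h (percentile 2.24), the core pluripotency list one of 0.10 in the re-addition after 24 h (percentile 99.0), and the reference genes one of 0.12 after 24 h (percentile 97.7), with 0 of 10 past 1.4-fold and a median of opposite sign when the probes of a gene were averaged. A rise near that size after 24 h, such as 0.15 for cell cycle genes, thus does not by itself set a list apart from the reference genes. Neural, p53, heat shock and glycolysis lists stayed within the central 95% in all 4 comparisons, with medians of -0.23, -0.01, -0.02 and 0.04 after 12 h.

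**Figure D3:**
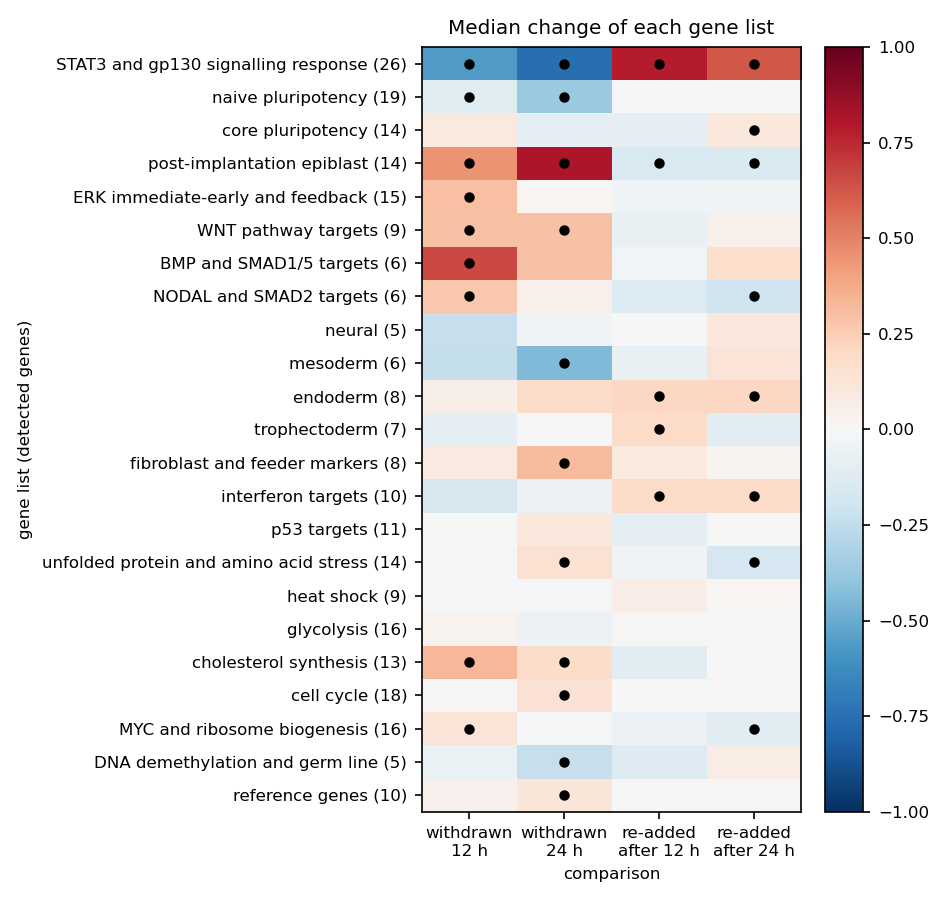
Median log2 change (colour) of each gene list (vertical axis, with the number of detected genes) in the 2 withdrawals and the 2 re-additions (horizontal axis), from 1 array per condition. Black dots mark the 33 of 92 medians outside the central 95% of random lists; the STAT3 and gp130 list had -0.56 and -0.75 in the withdrawals and 0.78 and 0.62 in the re-additions.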

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

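The test of the other Acta2 probes and the comparison of collagen signals were chosen only after the result was seen. The list of serum response factor and contractile genes used below was not among the gene lists fixed before the data were examined. Acta2, which encodes smooth muscle actin, went in opposite directions in the withdrawals: its log2 change from the maintained array was -0.79 after 12 h and 1.40 after 24 h, a difference of 2.19 between single arrays that was not tested. On the re-added arrays Acta2 was 0.45 above the maintained level after 12 h and 1.75 after 24 h, and Actc1 0.29 and 1.57. The higher level at 24 h was thus seen on both arrays of that duration. The fall at 12 h was not, as Acta2 rose by 1.24 in the re-addition after 12 h. A single faulty probe is argued against by the 3 other detected Acta2 probes, all of which passed 1.4-fold in both directions. Normalization is argued against by the difference of Acta2 under the other normalizations. It was 1.95 on the authors' values, 1.975 without background correction, 2.15 with a common median and 2.18 with cyclic loess. The remaining sets of values used the main normalization. No collagen rise went with that of Acta2: the signal of the 5 collagen probes rose by 1.6 at most, while that of Acta2 rose by 886. Col1a1, the only 1 of 3 collagen genes detected on any array, had a log2 difference of -0.09 between the withdrawn arrays. Its signals there were 97.6 and 90.1, neither above background. Of the other markers, Dcn had a log2 difference of -0.36 and Thy1 one of 0.49. Collagen probes at background, whose sensitivity is not known, do not settle whether fibroblasts or feeder cells were the source of the rise. Of 19 other serum response factor and contractile genes, 6 were higher and 0 lower at 24 h than at 12 h. Their median was 0.42, at percentile 100 of random lists (Myl9 1.58, Tagln 1.25). This list was scored on the same withdrawn arrays that gave the Acta2 result, so its percentile is not an independent check. A shift of the serum response factor and contractile programme stays a hypothesis. Ankrd1 of that list had been seen before, and other contractile cells were not tested. With 1 array per condition, a difference between the cultures other than the time without GCSF stays open as well.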

How the results depend on the processing

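No alternative in this part was chosen after the results were seen. Differences between 2 single arrays have no test, paired or not; the limma test of re-addition paired the withdrawn and re-added arrays by duration. Numbers of changed genes are in the order withdrawal 12 h against maintained, withdrawal 24 h against maintained, re-addition after 12 h against withdrawal 12 h, re-addition after 24 h against withdrawal 24 h, withdrawal 24 h against 12 h, re-added after 12 h against maintained, re-added after 24 h against maintained, and both arrays re-added against maintained (changed the same way); they were 1282, 1529, 962, 860, 1111, 1289, 1622 and 500, with 55 genes that fell then rose and 10 that rose then fell, 94 higher in both re-additions, and 0 by limma (1065 at an unadjusted p under 0.05). Correlations are in the order of the re-additions, withdrawal 12 h with re-addition after 24 h, and withdrawal 24 h with re-addition after 12 h, and were 0.17, -0.14 and -0.09. On the authors' deposited normalized values the numbers were 264, 332, 110, 69, 114, 164, 297 and 86, with 26 and 2 by the rule (all shared), 42 in both re-additions, correlations of 0.26, -0.20 and -0.12, and 116 by limma. With quantile normalization and no background correction they were 298, 362, 130, 77, 137, 187, 333 and 93, with 28 and 3 (all shared), 45, correlations of 0.25, -0.20 and -0.12, and 118 by limma. In the 4 withdrawals and re-additions every change called on the authors' values was also called in the main values, and the genes called in the main values alone after 12 h of withdrawal had a median signal of 108, against 379 for the shared ones, so signal over background limits the dim part of the counts; the cause of the other shifts under these sets of values was not tested. With probes detected on all 5 arrays, which leaves fewer genes, the numbers were 761, 935, 480, 352, 611, 710, 989 and 300, with 5 that rose then fell, correlations of 0.26, -0.20 and -0.12, and 44 by limma. With no detection filter the correlations were 0.11, -0.094 and -0.057, with 5 genes by limma, and with a common median the last correlation was -0.066; the cause was not tested. At 2-fold, by construction, the numbers were 120, 134, 48, 31, 30, 47, 105 and 19, with 12 and 0 by the rule and 18 in both re-additions, and at 1.2-fold 3893, 4259, 3396, 3062, 3750, 4033, 4577 and 1981, with 166 and 88 and 383. The mean of both re-added arrays against the maintained array gave 1026 genes. Pairs of comparisons, which ask for fewer changes than the 4-comparison rule, gave 114 and 48 for withdrawal 24 h with re-addition after 12 h, 99 and 35 for withdrawal 12 h with re-addition after 24 h, and, in pairs that share the withdrawn array, 195 and 157 for the 12 h pair alone and 162 and 142 for the 24 h pair alone, where simulated unchanged arrays gave 42.9 and 49.2, and 42.5 and 59.2. These simulated numbers can be too low, since genes noisy on every array are not reproduced and no noise of the maintained array enters them. By limma, cyclic loess gave 15 genes, no block 4, 3 states 4 and an intensity trend 136, and a common median, the mean of the probes and an adjusted p of 0.1 gave 0 each; the cause was not tested. The other numbers of changed genes stayed within 1.5 times the main ones with a common median, cyclic loess, no detection filter and the mean of the probes. Of the numbers of genes higher and lower taken separately, 70 left the range of 1.5 times the main number and 56 stayed in it. Of the list medians under the alternatives, 614 kept their side of the central 95% of random lists, 12 moved out of it and 14 into it. Of the changes of named genes 4138 kept their side of the threshold in use, 103 came past it, 367 no longer passed it, and 0 changed sign past it. The tallies of separate numbers and of named genes include the 1.2-fold and 2-fold thresholds, which move calls by construction. Neither tally is thus a measure of processing at 1.4-fold alone.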

Other observations

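The ratio for lower genes, the wrong-direction overlap and the grouping of assignments by the place of the withdrawn arrays were not among the tests set beforehand. The other tests in this part were. Noise of single arrays picked out by the rule is argued against as the source of the 55 genes that fell in both withdrawals and rose in both re-additions: 1 of the 60 assignments of the arrays, the actual one, gave a count as large, and the highest other gave 53. That other assignment also had the withdrawn arrays in the withdrawn places, where counts ran from 45 to 55, so the assignments set the withdrawn arrays apart from the rest and say little on which of the others was which. Between comparisons that share no array, the smaller ratio of genes that fell and then rose to the overlap of independent lists was 5.38 (114 genes against 21.2), while 29 against 17.6 overlapped in the wrong direction, so independent lists are too low a measure and part of the ratio is not a shared response. A response to GCSF may therefore underlie these genes, a hypothesis found and tested on the same arrays. An effect of handling at withdrawal and re-addition was not tested. For the 10 genes with the converse pattern 26 of the 60 assignments gave as many.

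Of the genes that fell in both withdrawals 64.5% passed 1.4-fold in neither re-addition, and 41.4% were still 1.4-fold below the maintained level on both re-added arrays; of those that rose in both, 69.4% and 37.8% did so. A noisy maintained array would give the same picture, since both withdrawals and both returns are measured against it. The number of genes at least 1.4-fold higher on the maintained array than on every other array was 154, and the highest number for another array was 63, a ratio of 2.44; for lower genes the ratio was 2.11. A ratio above 1.5 had been set to count against noise, but a noisier array would raise both numbers, so incomplete return and noise of the maintained array cannot be told apart here.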
